A study of Rattus norvegicus with 8 samples.

How the data were processed

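RNA from primary rat Sertoli cells was measured in 4 groups (control, NP, MBP and NP+MBP) on a gene-level Affymetrix array and on an Affymetrix microRNA array. Groups were taken from the sample titles. Each of the 8 samples was a different combination of group and array type, so the 2 samples of a group were not replicates of each other. Each table held 1 array per group. The 2 tables were normalized separately, and no level was compared across them.

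The gene-level values were log2 signals that the authors had summarised and normalized with gene-level RMA, per the file headers. The submitters' processing notes name MAS5, with no version, which disagrees with those headers. The values range from 1.94 to 13.46, as log2 data do, and RMA was taken as the method of this table. A deposited workbook held the same log2 values, with 0 cells differing by more than 1e-09. The microRNA values were also deposited by the authors on a log scale, taken here as log2 from their range of -0.94 to 13.94. Their summarisation and background correction are not given in the sources used here, and the base is an inference. No detection calls were used.

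Of 29214 gene-level probe sets, 27596 were not control sets (45 antigenomic, 1153 intronic, 399 exonic and 21 other control sets were set aside). Of these, 18771 had 1 gene symbol, 2013 several and 6812 none. Only sets with 1 symbol were named, and the set with the highest mean signal stood for its gene. Symbols were those of the workbook. They were looked up in an NCBI RefSeq table of assembly GRCr8 by symbol, accession and synonym, which matched 17673 of the 18771. Coordinates are those of the workbook. Of 24982 sets whose descriptions give RGSC3.4 positions, 97.5% overlapped them, so the coordinates are printed as RGSC3.4. No coordinate was taken from the RefSeq table.

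Probe sets were kept where the mean log2 signal over the 4 arrays was at or above the median of all non-control sets, 7.50, which left 13798 sets and 9998 named genes. Of the sets kept, 1435 are marked by the annotation as open to cross-hybridization. For microRNAs the filter was the median of the 680 mature rat rows, 1.35, which left 340. The other 486 rows were not used in the comparisons.

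Differences between arrays are log2 differences. With 1 array per group they have no test, and sets at least 2-fold apart were counted as a description. Each compound's difference was also taken over 2 pairs of arrays with none in common, as mean ± SD of the pairs. An additive model with the terms NP and MBP was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 1 residual degree of freedom and Benjamini-Hochberg adjusted p under 0.05. A true interaction counts as noise in this model. On simulated arrays of 13798 sets, with the fitted spread and 200 sets changed by MBP, it recovered 94.5% of the sets changed by 0.5 log2 with 10 false calls, and 100% of those changed by 1 log2 with 18 false calls. These rates hold for 200 changed sets and were not measured for fewer. A lack of calls in the real data therefore does not show that no set differed by 0.5 log2.

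For 39 lists of genes or microRNAs fixed before the data were examined, the median difference was set against 10000 random lists of the same size matched on mean signal in 20 bins. 1 list had no member above the filter. On simulated gene-level arrays with no effect, 2 of 78 list medians fell outside the central 95%, and a list of 23 genes raised by 0.1 log2 reached the 100th percentile. The correlation of the MBP pairs was -0.014 with no effect and 0.481 with 200 genes raised by 0.5. Chance correlation from the shared control array was simulated from an SD of 0.051 per array.

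The rule for the genes named was also fixed beforehand. It took the 10 highest and 10 lowest genes of each treatment against control, the 8 highest and 8 lowest in both pairs of each compound, and the 5 highest and 5 lowest departures from additivity. From each list described it took up to 4 members. On the microRNA array it took the 6 highest and 6 lowest of each comparison, and 4 and 4 over both pairs. Fixed control and Sertoli cell genes were given on every array. Not every gene taken by the rule is printed, and 1 of them is not reported here.

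Alternatives were median centring, quantile normalization and cyclic loess, no filter or a filter at the 75th percentile, a 1.5-fold threshold, the workbook values, the mean of all rows of a gene, and a prior that follows signal. Counts without the control array were added after seeing the data. Computations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.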

Results

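Sertoli cells, the somatic cells that nurse germ cells in the seminiferous tubule, were taken from rat testes and grown in primary culture. The cultures received solvent, 0.1 µM of a compound labelled NP, 0.1 mM of a compound labelled MBP, or both, for 24 hours. The labels do not spell out the abbreviations. The stated aim was to find genes and microRNAs whose expression differed between treated and control cells. Total RNA of the 4 groups was read on 2 array types, a gene-level array and a microRNA array, so the 8 samples gave 1 array per group on each type. No pairwise difference therefore had a replicate check, and the number of arrays limits the precision of every value.

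Each compound was present on 2 arrays and absent from 2, so its difference was read in 2 pairs that shared no array. For MBP these were MBP minus control and NP+MBP minus NP. For NP they were NP minus control and NP+MBP minus MBP. Values with an error are the mean of these pairs ± SD (n = 2 pairs), which also holds any true interaction of the compounds. The Sertoli cell genes Sox9, Wt1 and Clu were measured on every array. In the order control, NP, MBP and NP+MBP, the log2 signal of Sox9 was 10.62, 10.60, 10.65 and 10.63. Wt1 was at 9.69, 9.64, 9.81 and 9.77, and Clu at 11.45, 11.43, 11.53 and 11.53. The cytoskeletal control Actb was at 13.35, 13.32, 13.30 and 13.32. Gapdh had no probe set carrying its symbol alone and was not used.

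MBP alone was set against control to ask what that compound does by itself. Cldn11, a claudin of the tight junctions between Sertoli cells, was lower by 0.67 on the log2 scale, at 9.37 against 10.04 in control. Dpt, which encodes the matrix protein dermatopontin, was lower by 0.51, and Cd34, a surface glycoprotein, was lower by 0.38. On the other side, Scn3b, a sodium channel beta subunit, was higher by 0.70, Fgl2 by 0.61, and Myoz2, a protein of the muscle Z-disc, by 0.60. Efhd1 was higher by 0.59, Slc25a31, a mitochondrial ADP/ATP carrier of germ cells, by 0.56, Mmd2 by 0.54 and Nr0b2, an orphan nuclear receptor, by 0.53. Ret, a receptor for GDNF-family ligands, was higher by 0.52 and Tex15, a gene needed for meiosis, by 0.51. Among the other genes with the lowest differences were Vsig1 at -0.42, LOC685173 at -0.52, Il28b at -0.44 and Sp6 at -0.41. NP+MBP minus NP gave -0.54 for Vsig1, but -0.07 for LOC685173, -0.01 for Il28b and 0.01 for Sp6.

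Of 13798 gene-level probe sets above the signal filter, none differed by 2-fold or more between MBP and control. At 1.5-fold, 8 were higher and 1 was lower. Cldn11 was the lower one, and Scn3b, Fgl2, Myoz2 and Efhd1 were the 4 named genes among the higher ones. Without the control array, NP+MBP minus NP gave 5 such probe sets, all higher (chosen after seeing the data). Beside the germ cell genes among these, 30.0% of 10 premeiotic germ cell markers differed by more than 0.1 in the mean of the MBP pairs. This share decides neither way on germ cell content, and most of the 10 markers lay below the signal filter.

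The genes with the largest differences in the same direction in both MBP pairs were then taken. They were picked on both pairs, so their agreement between the pairs is not a separate check. Cldn11 differed by -0.62 ± 0.07 over both pairs, Dpt by -0.52 ± 0.02, Vsig1 by -0.48 ± 0.08 and Cd34 by -0.44 ± 0.09. Smaller differences were seen for Entpd2 (-0.30 ± 0.06), the secreted Wnt modulator Sfrp2 (-0.28 ± 0.03), the chemokine Ccl7 (-0.26 ± 0.01) and the proprotein convertase Pcsk5 (-0.23 ± 0.01). On the higher side, Myoz2 differed by 0.74 ± 0.20, Scn3b by 0.65 ± 0.08, Fgl2 by 0.62 ± 0.01 and the X-linked ubiquitin protease Usp26 by 0.59 ± 0.12. Slc25a31 stood at 0.58 ± 0.03, Efhd1 at 0.56 ± 0.05, Tex15 at 0.53 ± 0.02 and Mmd2 at 0.53 ± 0.02. In the coordinates of the array annotation, which its transcript descriptions assign to assembly RGSC3.4, the Cldn11 probe set spans chromosome 2 from 116626421 to 116639732. The Fgl2 probe set spans chromosome 4 from 9176331 to 9181977, and that of Dpt chromosome 13 from 80562950 to 80591363.

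**Figure D1:**
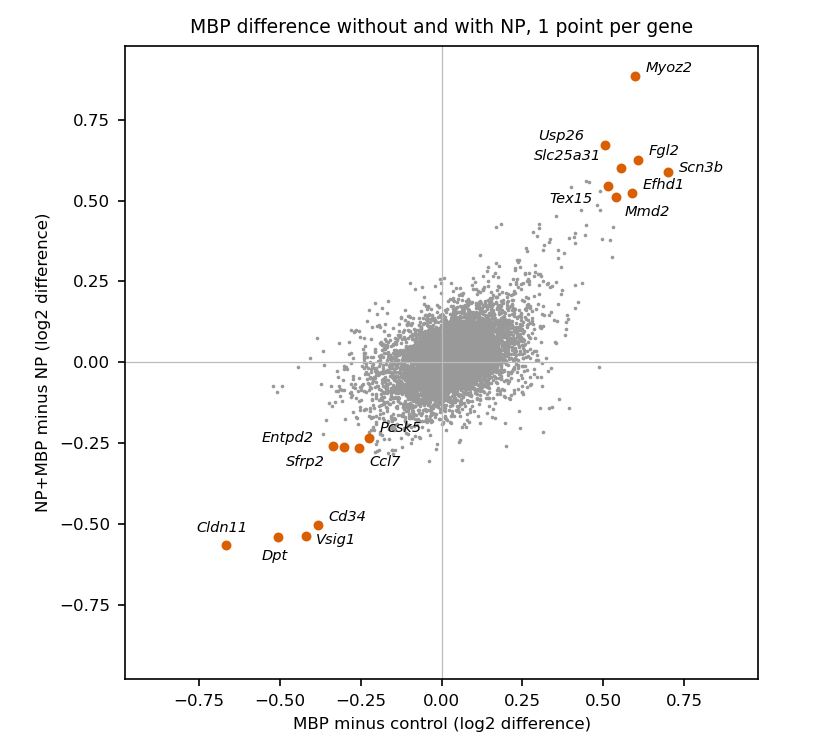
Each point is 1 of 9998 genes, with the log2 difference of MBP minus control on the horizontal axis and that of NP+MBP minus NP on the vertical axis; orange points are the 8 genes highest and the 8 lowest in both pairs. Cldn11 and Dpt lie far from the cloud at the lower left, and Myoz2, Scn3b and Fgl2 at the upper right.

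Across the 13798 probe sets, the 2 MBP differences correlated with r = 0.42, and across the 9998 named genes with r = 0.49. These correlations are across genes, which are not independent replicates. Without a signal filter, r was 0.187. In limma's additive model, which takes the departure from additivity as its error, no probe set reached an adjusted p under 0.05 for MBP. The smallest adjusted p was 0.081, shared by the named genes Cldn11, Dpt, Fgl2, Scn3b, Efhd1, Mmd2, Slc25a31, Tex15, Kcne1, Dapp1 and Pla2g7, and 2110 probe sets had an unadjusted p under 0.05. The number of probe sets with an adjusted p under 0.05 depended on the setting. It was 117 after each array was centred on its median, 100 with a signal-dependent prior and 11 above the 75th percentile of signal. It was 0 after quantile or cyclic loess normalization or with no filter.

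**Figure D2:**
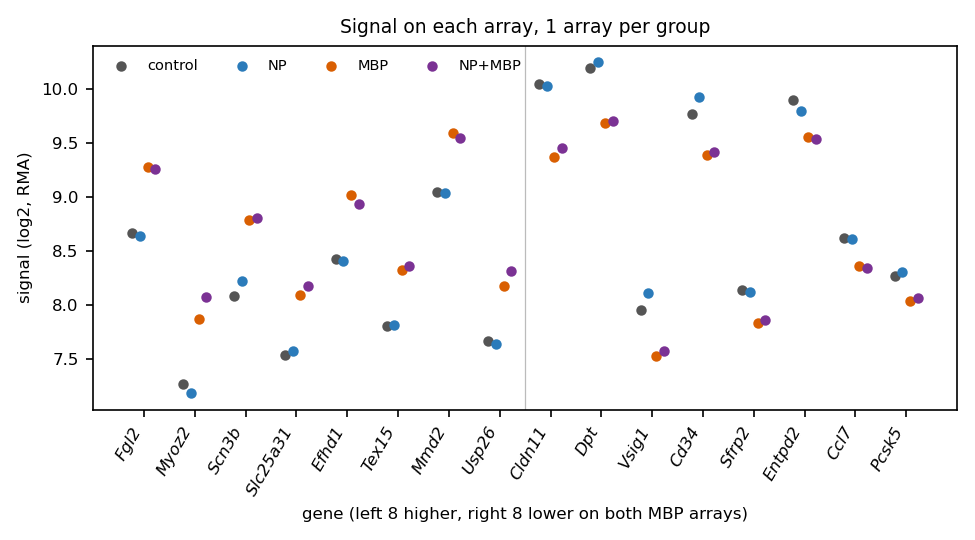
Log2 signal of the 8 genes highest and the 8 lowest in both MBP pairs, 1 point per array; the left 8 were higher and the right 8 lower on both arrays with MBP. For Cldn11 the arrays without MBP read 10.04 and 10.02 and those with MBP 9.37 and 9.46.

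NP alone gave no 2-fold difference from control in any of the 13798 probe sets. Among the highest named genes were Trnt1, which adds the CCA end to tRNAs, at 0.55 and the spliceosomal Snrpf at 0.50. Ubxn2a followed at 0.44, the centromere protein gene Itgb3bp at 0.43 and Magoh, of the exon junction complex, at 0.40. Among the lowest were Il28b at -0.56, Tnfrsf25 at -0.39, Rnf183 at -0.39 and Kcnk4 at -0.35. In the second pair, NP+MBP minus MBP, the differences were 0.02 for Trnt1, 0.00 for Snrpf, 0.16 for Magoh and -0.13 for Il28b. At 1.5-fold, 9 probe sets were higher and 1 was lower, none of them a named gene, against 4 higher ones without the control array (chosen after seeing the data).

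Other genes differed in the same direction in both NP pairs. They were picked on both pairs, so neither their agreement nor a small SD between the pairs is a separate check. LOC690096 was highest at 0.35 ± 0.03, followed by Poli, a translesion DNA polymerase, at 0.25 ± 0.03, Vsnl1 at 0.24 ± 0.03 and Thumpd3 at 0.23 ± 0.01. Rad51c, of homologous recombination, stood at 0.22 ± 0.00, and Casc5, now named Knl1, a kinetochore gene, at 0.24 ± 0.04. On the lower side were Acpt, now named Acp4, at -0.29 ± 0.02, Hoxd1 at -0.26 ± 0.06, Foxd3 at -0.26 ± 0.09, Aanat, which acts in melatonin synthesis, at -0.23 ± 0.02 and the Leydig cell hormone gene Insl3 at -0.19 ± 0.00. The row carrying the symbol Ttr, at 0.22 ± 0.01, is placed on the mitochondrial chromosome by the annotation, so its gene name is uncertain.

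Across probe sets the 2 NP differences correlated with r = 0.38, again across genes. Limma's additive model called no probe set for NP, with a smallest adjusted p of 0.203 and 1630 unadjusted p under 0.05. Other settings gave 23 calls with median centring, 13 with no filter, 5 with a signal-dependent prior and 1 above the 75th percentile. Quantile and cyclic loess normalization gave 0. The antigenomic probe sets, which match no rat transcript, were lower than control on the NP array with a median difference of -0.109 (SD over sets 0.079, 45 sets).

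With both compounds, the highest named genes against control were Myoz2 at 0.80, Scn3b at 0.72, Usp26 at 0.65, Slc25a31 at 0.64, Fgl2 at 0.59 and Dapp1 at 0.59. Pla2g7, which degrades platelet-activating factor, was higher by 0.58, the potassium channel subunit Kcne1 by 0.57, and Tex15 and the piRNA pathway gene Mael by 0.55 each. Among the lowest were Cldn11 at -0.58, Il28b at -0.57, Dpt at -0.48, Mir504 at -0.45 and the somatostatin gene Sst at -0.41. Of 13798 probe sets, 2 were at least 2-fold higher and 0 lower. Neither had a symbol: 1 reads the mitochondrial tRNA-Glu, at 1.02, and 1 lies on chromosome 12 from 4774673 to 4775272, with a signal of 8.26 against 7.26 in control (both singled out after their values were seen). With no signal filter the count was 30.

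The 3 comparisons used 1 control array. Over the 13798 probe sets, differences from it had an SD of 0.106 for NP, 0.105 for MBP and 0.129 for NP+MBP, against 0.064 for NP+MBP minus MBP and 0.078 for NP+MBP minus NP. The differences of NP and of MBP from it correlated with r = 0.75 across probe sets, against 0.51 in simulated arrays with no effect, and with a covariance of 0.00832 against 0.00261. For NP and NP+MBP, r was 0.79 and the covariance 0.0109, against 0.00254 simulated, and for MBP and NP+MBP r was 0.87 and the covariance 0.0118, against 0.00255. Of the probe sets at least 1.5-fold higher, 2 were shared by NP and MBP, where independent lists of 9 and 8 would share 0.0052. NP and NP+MBP shared 6, with 0.0189 for independent lists, and MBP and NP+MBP shared 7, with 0.0168. Correlations and overlaps that share an array are not independent, and the control array could not be split. The simulated arrays all had the same SD of 0.051. A control array that varied more than the others could therefore not be told apart from a shared effect.

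The departure from additivity asks whether the pair of compounds differed from the sum of each. It was largest on the positive side for Kcng4 (0.46), LOC685173 (0.45), Il28b (0.43), Mir504 (0.42) and Sp6 (0.42). Among the most negative were Trnt1 (-0.53), Snrpf (-0.50), Fbrs (-0.48) and Zfp280b (-0.48). In each of these genes the control array lay to 1 side of all 3 treated arrays. Over the 13798 probe sets the departure had an SD of 0.101, and limma called none when either compound served as the error, with 135 and 152 unadjusted p under 0.05. Such a fit takes the whole effect of that compound as noise, with 1 residual degree of freedom. The lack of calls therefore does not show that the compounds were additive.

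Cell cycle genes stood above matched random lists in every comparison. Of 25 measured members, 22 were higher on the NP array than on the control array, 24 on the MBP array and 24 on the NP+MBP array, none by 1.5-fold. Of all 13798 probe sets, 8604, 8848 and 8960 were higher in these comparisons. The list medians were 0.07, 0.12 and 0.13, at the 98.9th, 100th and 99.95th percentile of 10000 random lists matched on signal. Without the control array, the medians were 0.04 for NP+MBP minus MBP and 0.06 for NP+MBP minus NP, at the 99.6th and 99.8th percentile. Examples on the NP+MBP array were Ttk at 0.43, Nusap1 at 0.35, Bub1 at 0.33 and Ccna2 at 0.31.

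Genes of cholesterol synthesis and uptake had a median of -0.029 for MBP and -0.028 for NP+MBP, below the 0.1th percentile, with 3 of 18 members above 0 in each. Centring the arrays turned these medians to 0.002 and 0.004 and left them below nearly all random lists. Sqle, which encodes squalene epoxidase, stood at -0.13 for MBP, Fdft1 at -0.10 and Dhcr7 at -0.09. For NP+MBP minus NP, which leaves out the control array, the list median was -0.043 and no random list was lower.

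Blood-testis barrier and junction genes differed in both directions. Cldn11 was the 1 member of 21 past 1.5-fold for MBP, whereas Itga6 was higher by 0.33, occludin (Ocln) by 0.31 and F11r by 0.26. On the NP+MBP array Ocln and Itga6 were higher by 0.43 each and Dsg2 by 0.31, and the list median of 0.08 lay at the 98.6th percentile. The list stayed inside random lists for NP (0.01, 31.8th percentile), for MBP (0.03, 62.5th) and for NP+MBP minus MBP (0.02, 77.2th), but not for NP+MBP minus NP (0.08, 100th). Sertoli cell markers had medians of 0.01, 0.01 and 0.03 for NP, MBP and NP+MBP, at the 27.9th, 31.9th and 42.6th percentile. Cldn11 was again the 1 of 23 members past 1.5-fold, for MBP.

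Inflammatory and NF-kB targets had medians of -0.04, -0.07 and -0.09 in the 3 comparisons, at or below the 0.6th percentile, over 8 members, of which 4, 2 and 3 lay above 0. Cxcl10 stood at 0.42 for MBP, Ccl2 at -0.23 and Cxcl1 at -0.18. Without the control array the list lay at the 2.6th percentile for NP+MBP minus MBP and at the 22.8th for NP+MBP minus NP. Leydig cell and steroidogenesis genes had medians of -0.07 for NP and -0.06 for MBP over 9 members, at the 0.2th and 0.9th percentile. These medians turned to 0.004 and 0.015 above the 75th percentile of signal. The median was -0.04 for NP+MBP against control, at the 4.0th percentile, -0.05 for NP+MBP minus MBP, at the 0.6th, and -0.01 for NP+MBP minus NP, at the 20.1th. Insl3 at -0.19 and Fdxr at -0.11 were the lowest of them for NP. Germ cell markers (6 members), peritubular myoid markers (11), macrophage markers (2) and endothelial markers (2) all lay inside the central 95% of random lists in the 3 comparisons with control. Without the control array, germ cell markers stood at -0.06 for NP+MBP minus MBP, at the 2.2th percentile, peritubular myoid markers at -0.01, at the 1.1th, and macrophage markers at 0.19 for NP+MBP minus NP, at the 98.4th, all outside it.

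Of 114 list medians, 15 lay outside the central 95% of random lists, where 5.7 would by chance if genes and comparisons were independent. The 3 comparisons share the control array and genes of a list can vary together, so this chance count is only a guide. Immediate early genes for NP, at -0.04, were among these, turning to 0.03 above the 75th percentile of signal. In the second NP pair they stood at -0.01, at the 9.4th percentile. Matrix and TGF-beta target genes for NP+MBP, at -0.01, were also among them, turning to 0.02 when arrays were centred. Oestrogen-responsive genes, PPAR targets, NRF2 genes, the unfolded protein response, heat shock genes, p53 targets and ribosomal proteins were inside in the 3 comparisons with control. NRF2 genes lay outside for NP+MBP minus MBP, at 0.03 and the 98.6th percentile.

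**Figure D3:**
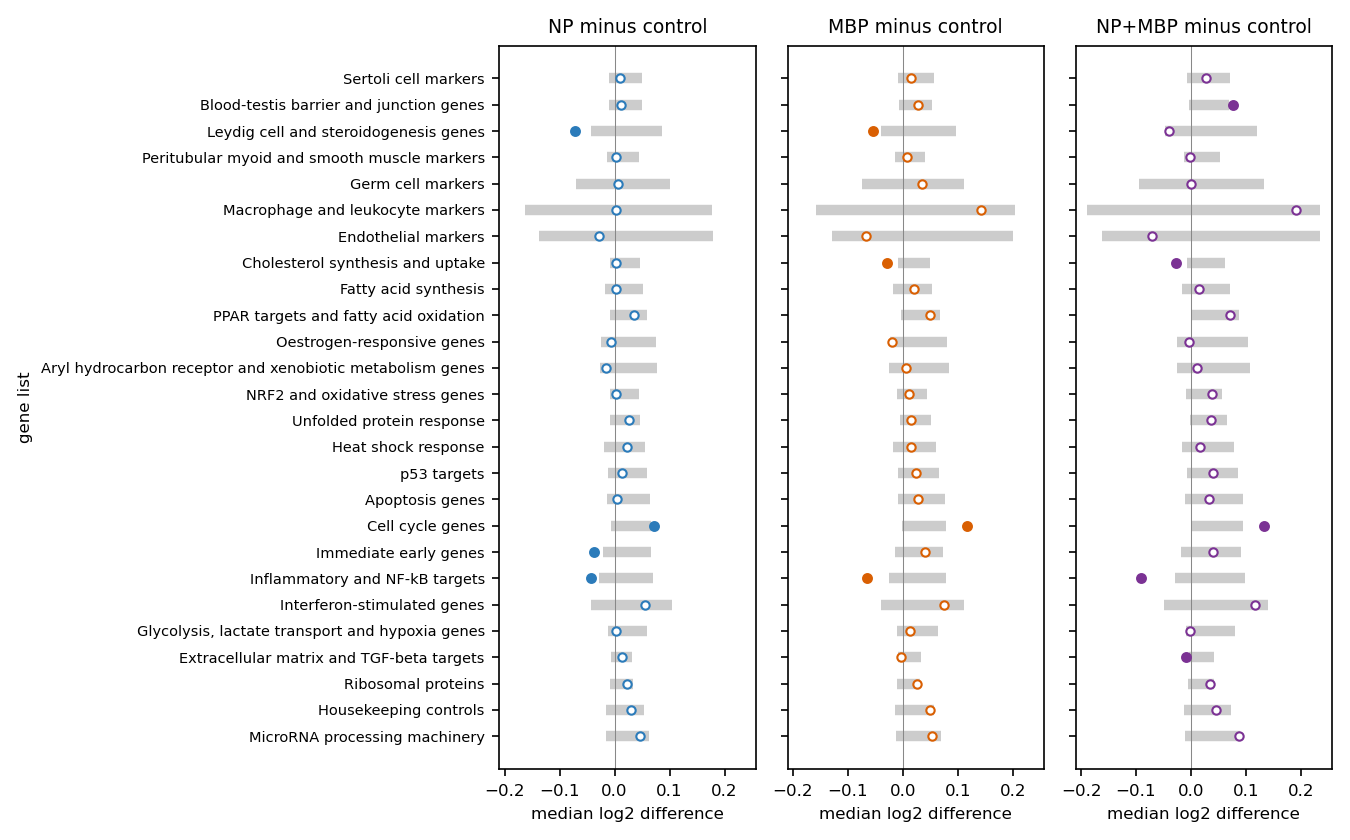
Median log2 difference from control of each gene list (circles), 1 panel per treatment, with grey bars for the central 95% of 10000 random lists matched on signal; filled circles lie outside it. Cell cycle genes lie to the right in all 3 panels, at 0.07, 0.12 and 0.13.

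On the microRNA array, 340 of 680 mature rat microRNAs were at or above the signal filter, a log signal of 1.35 in the mean of the arrays. A microRNA above it could still read lower on a single array, where its signal was not shown to exceed background. For MBP against control, miR-429 was higher by 2.40, miR-154-star by 2.28, miR-292-3p by 1.78 and miR-7a by 1.61. NP+MBP minus NP gave 0.08 for miR-429, 0.68 for miR-154-star and 0.53 for miR-292-3p. The control signals of miR-429, 0.68, and miR-154-star, 0.88, were below the filter, so the sizes of their differences are uncertain. The lowest were miR-483-star at -1.45, miR-195-star at -1.28, miR-466b-1-star at -1.27, miR-32-star at -1.23 and miR-466c-star at -1.19. In all, 21 were at least 2-fold higher and 7 lower, and above the 75th percentile of signal 0 and 2. Without the control array, NP+MBP minus NP gave 21 higher and 19 lower (chosen after seeing the data). Against control, the split moved to 14 and 11 with median centring, 14 and 13 with quantile normalization and 13 and 12 with cyclic loess.

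The miR-466 star forms were lower in both MBP pairs. The microRNAs given here were picked on both pairs, so neither their agreement nor a small SD is a separate check. miR-466b-1-star stood at -1.44 ± 0.25, miR-466b-2-star at -1.40 ± 0.30 and miR-466c-star at -1.20 ± 0.02. The signal of miR-466b-1-star was 8.06 in control, 8.25 with NP, 6.80 with MBP and 6.63 with both. miR-7a was higher by 1.55 ± 0.08, miR-455 by 1.15 ± 0.16, miR-872 by 1.12 ± 0.10 and miR-450a by 1.03 ± 0.00.

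For NP against control, 4 microRNAs were at least 2-fold higher and 10 lower. The highest was miR-678 at 1.23, and the lowest were miR-133a at -1.92, miR-493-star at -1.55 and miR-379-star at -1.54. On the NP array miR-133a read 0.72 and miR-493-star 0.32, below the filter, so the sizes of their differences are uncertain. Over both pairs, miR-29b stood at -1.08 ± 0.08, miR-493-star at -1.37 ± 0.26 and miR-370 at 0.63 ± 0.06, again picked on both pairs. Above the 75th percentile of signal no microRNA differed by 2-fold, and without the control array the counts were 2 higher and 20 lower (a comparison chosen after seeing the data).

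With both compounds, 9 microRNAs were at least 2-fold higher and 13 lower than control. miR-433-star was higher by 1.49, miR-615 by 1.43, miR-742 and miR-743b by 1.34 each and miR-871 by 1.17. At the other end were miR-32-star at -2.26, miR-466b-2-star at -2.03 and miR-195-star at -1.59. The control signals of miR-433-star, 0.50, and miR-615, 1.09, and the NP+MBP signal of miR-195-star, 0.76, were below the filter too. Above the 75th percentile 2 were 2-fold apart, both lower. Across the 340 microRNAs the 2 MBP differences correlated with r = 0.43 and the 2 NP differences with r = 0.17. Across the 170 microRNAs above the 75th percentile of signal, r was 0.60 for MBP and 0.46 for NP. The miR-30 family was the list with the lowest percentile for NP, at -0.18 and the 0.1th percentile over 6 members, against -0.01 and the 15.3th percentile for NP+MBP minus MBP. It stood at 0.22 for MBP, at the 95.9th percentile, and at 0.33 for NP+MBP minus NP, at the 99.5th. The let-7 family lay inside the central 95% in the 3 comparisons.

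**Figure D4:**
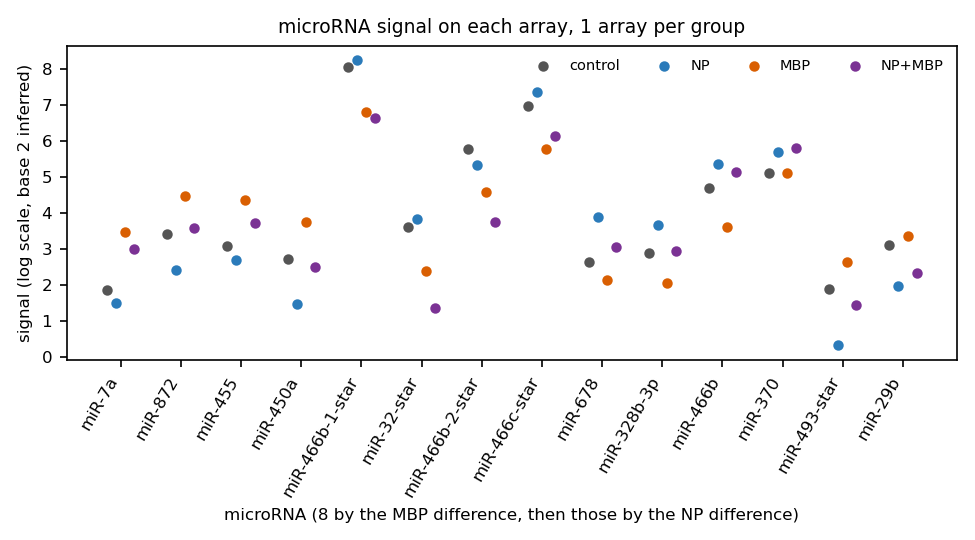
Signal of 14 microRNAs among the highest or lowest in both pairs of a compound, 1 point per array, on a log scale whose base is inferred to be 2. The points of miR-466b-1-star read 8.06, 8.25, 6.80 and 6.63 in the order control, NP, MBP and NP+MBP.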

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

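The tests of late and premeiotic germ cells, of intronic and antigenomic control sets and of shared probes were chosen only after the results had been seen.

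Several genes best known from germ cells, grouped after their values were seen, were higher on both arrays with MBP, namely Tex15 (0.53 ± 0.02), Slc25a31 (0.58 ± 0.03), Usp26 (0.59 ± 0.12), Mael (0.47 ± 0.10) and, below the signal filter, Dazl (0.85 ± 0.10, SD over n = 2 pairs), whereas the fixed germ cell list lay inside random lists (medians 0.04 and -0.01, at the 66.3th and 38.1th percentile, in the MBP pairs). Late germ cells such as spermatids are argued against, since Prm1, Prm2, Tnp1 and Acr had a median MBP difference of -0.024 (SD 0.093, 4 genes). Their mean signals were 8.12, 7.71, 6.57 and 6.35. Tnp1 and Acr lay below the filter, so this rests mainly on Prm1 and Prm2. Meiotic germ cells were not tested. Non-specific hybridization stays open. The 2 MBP differences of 239 intronic control sets correlated with r = 0.021. Their SDs were 0.234 and 0.174, against 0.105 and 0.078 over the 13798 probe sets. A shared difference as small as that of the probe sets could therefore be missed. The antigenomic sets were lower, by medians of -0.057 and -0.0185 in the pairs, opposite in direction to these genes, though their differences correlated with r = 0.302. More premeiotic germ cells may still be present, because 30.0% of 10 such markers (Dazl, Mael and Gfra1) differed by more than 0.1, a share that decides neither way. In these cultures 4 of the 10 were above the filter, Uchl1 at 11.09 among them. Of these 4, Mael and Gfra1 differed by more than 0.1, whereas Uchl1 (-0.01 ± 0.03) and Id4 (0.02 ± 0.06) did not. The signal of Uchl1 lay between those of the Sertoli cell genes Sox9 and Clu on every array. Whether it tracks germ cells in these cultures was not shown, so its small difference does not weigh on the question. A direct response of the Sertoli cells to MBP stays open as an untested hypothesis.

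Small differences on both NP arrays, such as Poli (0.25 ± 0.03) and Acpt (-0.29 ± 0.02), could come from dim signal or from background. A trend limited to dim sets is argued against for small differences over many genes, since the 2 NP differences of 5145 genes above the 75th percentile still correlated with r = 0.301. Of these 5145 genes, 6 were past 0.3 in the first NP pair, against 85 of all 9998 genes. The correlation therefore does not settle the larger differences or single genes. Background stays open: 66.7% of 45 antigenomic sets moved the same way in both NP pairs, all 30 of them downward. This share lies between the bounds set for either answer. The 9 sets with no difference in a pair were counted as not moving the same way, and the undecided result depends on that count. The NP differences of 239 intronic control sets above the filter correlated with r = 0.194. Those of the antigenomic sets correlated with r = 0.714, which goes with background. An action of NP was not tested apart from it.

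Outside the named genes, 65 snoRNA probe sets on chromosome 1, from 110837412 to 111484229, had a median NP difference of 0.51 (SD 0.594) in the mean of the pairs, and 16 were past 2-fold in both. All 16 lay below the signal filter, which 13 of the 65 passed, and the median signal of the 65 sets, 4.71, was below the antigenomic median of each array (5.11 to 5.37), so background stays open. A gain of snoRNA in general in the NP samples is argued against by the 419 other snoRNA sets, 174 of them above the filter. Their median NP difference was 0.015 (SD 0.124). With the 626 snRNA sets, 1045 in all, it was 0.008 (SD 0.133). The snRNA sets had a median signal of 4.50, also below the antigenomic medians, and 35 passed the filter, so they could hardly show a gain. In contrast, the 21 mitochondrial tRNA sets stood at 0.217 (SD 0.155). Sets that share probes may inflate the count: the 65 sets held 44 distinct value vectors, which decides neither way, and the 16 sets past 2-fold held 5. No biological explanation was tested.

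The 1153 intronic control sets, which are not gene measurements, were above the control array by a median of 0.136 with NP, 0.0805 with MBP and 0.125 with NP+MBP. The 21 mitochondrial tRNA sets were above it by a median of 0.38 with NP+MBP, 0.32 with NP and 0.24 with MBP.

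Some dim microRNAs differed in opposite directions in the pairs of a compound, a difference that was not tested. For NP, the pair without MBP and the pair with it gave 0.84 and -1.71 for miR-152-star, 1.12 and -1.68 for miR-380-star, 0.62 and -1.70 for miR-429, and 0.79 and -0.61 for miR-667-star. For MBP, the pair without NP and the pair with it gave 0.66 and -1.88 for miR-152-star and 1.29 and -1.51 for miR-380-star.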

How the results depend on the processing

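No paired analysis was possible because each table held 1 array per group and the titles carry no numbers that pair samples. No array could be left out of the additive model, which has 1 residual degree of freedom. Detection calls and a pseudocount of 16 on linear values were not run, since the tables used here hold log values without calls. The 2-fold counts on the gene-level array were the same under median centring, quantile normalization, cyclic loess and the workbook values, and without the control array for NP and for MBP (chosen after seeing the data). For the changes below, the cause was not tested unless stated. With no filter, which adds dim sets, the counts for NP, MBP and NP+MBP were 24, 4 and 30 on the gene-level array, and 27 for NP and 36 for NP+MBP on the microRNA array. The correlation of the pairs was then 0.187 for MBP and 0.296 for NP, and limma called 13 sets for NP. Above the 75th percentile, where fewer sets were tested, NP+MBP had 0 gene-level sets, and NP, MBP and NP+MBP had 0, 2 and 2 microRNAs. The NP correlation was 0.306, limma called 11 sets for MBP and 1 for NP, and 8 list medians were outside random lists against 14 over the same lists. A 1.5-fold threshold gave 10, 9 and 31 gene-level sets and 51, 78 and 60 microRNAs. Averaging the rows of a gene left 0 gene-level calls for NP+MBP, where only named genes remain, and 6, 11 and 6 microRNAs. Median centring gave 117 limma calls for MBP and 23 for NP, and a prior that follows signal 100 and 5. Without the control array, 22 microRNAs differed for NP (chosen after seeing the data). Centring reversed the cholesterol list (0.002 for MBP, 0.004 for NP+MBP) and the matrix list (0.024 for NP+MBP). Above the 75th percentile the Leydig list (0.004 for NP, 0.015 for MBP) and the immediate early list (0.029 for NP) reversed. Of the list medians under all alternatives, 679 kept their side and direction, 16 moved inside random lists and 10 outside. Signal over background, not measured on the microRNA array here, limits the microRNA counts.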

Other observations

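The test of the X chromosome cluster was chosen only after the result had been seen.

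Apoptosis genes held a few members that were higher with MBP although the list stayed within random lists, at a median of 0.03 over 19 members for MBP. The survival gene Bcl2 was higher than control by 0.30 with MBP and 0.37 with NP+MBP, and the pro-apoptotic Bcl2l11 by 0.23 and 0.20. Interferon-stimulated genes had a median of 0.12 over 7 members with NP+MBP, at the 94th percentile, with Ifit2 at 0.21 and Ifit1 and Gbp2 at 0.17 each. The median was 0.06 for NP+MBP minus MBP, at the 97.6th percentile, and -0.0045 for NP+MBP minus NP, at the 26.4th.

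MicroRNAs of a cluster on the X chromosome were mostly higher on the arrays with MBP. The hypothesis was that the cluster differs as a unit. Of 12 microRNAs above the filter, from 14 neighbouring genes, 11 were higher for MBP against control, with a median of 0.52, and 10 for NP+MBP minus NP, with a median of 0.997. Chance may account for this, since the first median lay at the 93.55th percentile of random sets matched on signal, inside their central 95%. The second lay at the 99.97th percentile, and for NP+MBP against control the median was 0.69, at the 99.94th, with 12 of 12 higher. Both of these comparisons share the NP+MBP array, and the cluster was picked after values had been seen. Neighbouring microRNAs can vary together, so chance was not excluded in any comparison. For NP the cluster had a median of 0.34 in NP+MBP minus MBP, at the 99.4th percentile, and of -0.16 against control, at the 11.7th. miR-742 read 2.21, 2.35, 3.22 and 3.55 and miR-871 4.21, 4.07, 4.92 and 5.38 in the order control, NP, MBP and NP+MBP.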
